A study of Mus musculus with 2 samples.

How the data were processed

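Whole spinal cords of AR-97Q and AR-24Q mice were profiled by single-nucleus RNA sequencing at 6 weeks of age, a stage the labels place before disease onset. Per the labels' protocols, the cords of 4 mice per genotype were combined before nuclear isolation, so each genotype is 1 library and its value is already an average over animals. Frozen tissue was homogenised in a detergent buffer, debris was removed, and DAPI-stained nuclei were sorted before loading on the 10x Chromium 3' v3.1 platform, per the labels. Sequencing used an Illumina instrument with a Read 1 of 28 bp and a Read 2 of 90 bp, at a stated minimum of 20000 reads per nucleus. The sort and the isolation select what is counted, so a share of nuclei is a share of recovered nuclei and not of the cells in the cord.

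The authors deposited, for each library, a matrix of UMI counts per gene and barcode. Per the submitters' processing notes these counts came from Cell Ranger 5.0.1 with the mm10 reference, and per the labels both introns and exons were counted. The annotation release, whether the human transgene was part of the reference, and whether counting used the strand are not given in the sources used here. Counting introns adds unspliced nuclear RNA and favours long genes, and UMIs remove copies made by amplification. Symbols and identifiers were taken from the deposited gene index of 32285 genes. Gene positions came from GENCODE vM21 (GRCm38), in which 32158 of those identifiers were found. For 40 entries that repeated a symbol listed before, the entry listed earliest was used. Counts of overlapping genes can be assigned to either gene and are treated as uncertain.

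The AR-24Q matrix held 8638 barcodes with 53020916 UMIs and the AR-97Q matrix held 11345 barcodes with 75311422 UMIs. Nuclei with at least 500 genes and at most 5% mitochondrially encoded UMIs were kept, which left 8577 and 11172. Doublets were called with Scrublet (scanpy 1.11.5) in each library, with an expected rate of 8.0%. It marked 430 barcodes (4.98%) of AR-24Q and 874 (7.70%) of AR-97Q. Called nuclei were left out together with clusters in which over 50% of nuclei were called, which took 25 and 31 further nuclei and left 8125 and 10281. Counts were normalised to 10000 per nucleus, log-transformed and reduced to 30 principal components over 3000 genes variable within each library, with no integration. Clusters came from the Leiden method (leidenalg 0.10.2, resolution 1.0) on a graph of shared neighbours among 20 nearest neighbours.

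The 38 clusters were named from marker genes fixed before the data were examined, and a class is called by its name followed by "-like". The scoring rule that joins markers to clusters was set after the clusters had been seen. A cluster took the class with the highest mean marker level and kept the name if at least 3 of its markers were detected in 10% of its nuclei at 1.5 times their level elsewhere. It also had to hold no more markers of another class than of its own among its 10 genes of highest fold. Neuronal clusters were those with a mean neuron marker level of at least 0.3 of the highest cluster. Neuronal nuclei were clustered again into 32 groups, which were called excitatory-like or inhibitory-like where the transmitter genes of that kind were detected at 3 times the share of the other. Clusters that failed these thresholds stayed unnamed and out of every class. They held 3.30% of nuclei in AR-24Q and 3.30% in AR-97Q. Of these, 183 and 233 nuclei came from 2 neuronal subclusters with more glial than neuronal markers among their leading genes. A subcluster of 139 and 164 nuclei had 8 inhibitory markers and was set aside for the astrocyte marker Slc4a4, so the inhibitory-like class leaves it out. The other, of 44 and 69 nuclei, was led by oligodendrocyte genes. Neuron-like nuclei of unnamed kind numbered 1012 and 1462.

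With 1 library per genotype no test can be made, nuclei are not replicates, and no p-value, standard error or number of changed genes is given. For each class with at least 100 nuclei in each library, UMI counts were summed per library and expressed as CPM, the usual rate per summed UMIs, with the class's own sum as the total. A CPM has an exact Poisson 95% interval, a ratio of CPM (AR-97Q over AR-24Q) an exact conditional binomial 95% interval, and a share of nuclei an exact Clopper-Pearson 95% interval. Differences of shares have a Newcombe interval built from Wilson bounds. All of these cover counting error only.

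Genes were named by a rule fixed before the data were examined. Genes with a CPM of at least 50 in 1 or both libraries and a summed count of at least 100 were ranked by ratio. In oligodendrocyte-like nuclei the 12 highest and 12 lowest were named and in each other class the 5 highest and 5 lowest, where the ratio was at least 1.5-fold either way and its interval excluded 1. Mitochondrially encoded genes, Xist, Y-linked genes, haemoglobin genes and unnamed gene models were kept out of that ranking. The ratio over all nuclei outside the class was computed beside each. For 33 gene lists, also fixed beforehand, the median log2 ratio over members with a summed count of at least 20 was computed with a prior count of 0.5. An interval came from 1000 Poisson draws. A percentile among 10000 random lists of the same size, matched over 20 bins of mean expression, describes where the list stood in these 2 libraries and is not a test. Up to 2 members with the highest and 2 with the lowest ratio of each list could be named. All 263 list and class pairs with a measured member were computed. Of these, 84 were recomputed under the alternatives that apply to their class, where these left a measured member, and the pairs the text gives were chosen after all values had been seen.

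The alternatives fixed beforehand were other filters on nuclei, doublet calls kept in, Leiden resolutions of 0.5 and 2.0, genes scaled within each library, scaling to a median ratio of 1, the mean over nuclei, thinning to a fixed number of UMIs, and other minimum counts. The leaving out of an oligodendrocyte-like cluster, the leaving out of a neuron-like cluster and the averaging of ratios within clusters were added after the data had been seen. The ratio, interval and list steps were tested on simulated counts of the oligodendrocyte-like class. Both simulated libraries were Poisson draws from a shared profile, with no spread between animals, nuclei or clusters. The results therefore check the computation under counting error and say nothing on differences between real pools. There 95.0% of the intervals over 3649 genes covered the simulated ratio. Of the changed genes, 35.8% of 67 with a fold of 1.5, 100% of 67 with a fold of 2.0 and 100% of 66 with a fold of 4.0 passed the naming threshold in the right direction, and 0 of 3449 unchanged genes did. Of 200 simulated lists without a shift, 95.5% lay within the central 95% of their random lists, and list intervals covered a simulated shift of 0.3 in 99% of lists. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.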

Results

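Nuclei from the spinal cords of AR-97Q and AR-24Q mice were compared before onset of disease. AR-97Q mice carry a human androgen receptor transgene with a tract of 97 glutamines and model spinal and bulbar muscular atrophy, an inherited motor neuron disease. AR-24Q mice carry the receptor with a tract of 24 glutamines and serve as the control. The comparison asks in which cell classes expression differed at 6 weeks. Each genotype was 1 library of 4 pooled mice, so no difference below has a replicate check and every interval covers counting error only. The AR-24Q library held 8125 analysed nuclei with 48259967 UMIs and the AR-97Q library 10281 nuclei with 65440093 UMIs. The median nucleus held 3877 UMIs and 1930 genes in AR-24Q and 4381 UMIs and 2131 genes in AR-97Q. After every nucleus was thinned to 2541 UMIs, which left out 2195 and 2406 shallower nuclei, the median was 1485 genes in both libraries.

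Neuron-like nuclei took a larger share of the AR-97Q library and oligodendrocyte-like and microglia-like nuclei a smaller share. Neuron-like nuclei made up 39.8% (95% interval 38.9 to 40.8) of AR-97Q and 35.7% (34.7 to 36.8) of AR-24Q, a difference of 4.12 percentage points (2.71 to 5.53). Oligodendrocyte-like nuclei made up 36.9% (35.9 to 37.8) against 40.9% (39.8 to 41.9). Microglia-like nuclei made up 2.95% (2.63 to 3.29) against 3.78% (3.37 to 4.22). Astrocyte-like nuclei stood at 9.91% in AR-97Q and 8.90% in AR-24Q. For oligodendrocyte precursor-like nuclei (4.35% and 4.74%), newly formed oligodendrocyte-like nuclei (1.27% and 1.29%) and cholinergic or motor neuron-like nuclei (0.554% and 0.603%, from 57 and 49 nuclei) no difference was detectable at this depth. Endothelial-like, pericyte or smooth muscle-like, ependymal-like and fibroblast-like nuclei were each under 1% of either library. The nuclei were sorted on DAPI and the shares follow what the sort recovered. With doublet calls kept in, the neuron-like difference was 1.99 percentage points. The neuron-like cluster of lowest depth, with a median of 1565.5 UMIs, held 130 nuclei of AR-24Q and 272 of AR-97Q and adds to the difference.

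**Figure D1:**
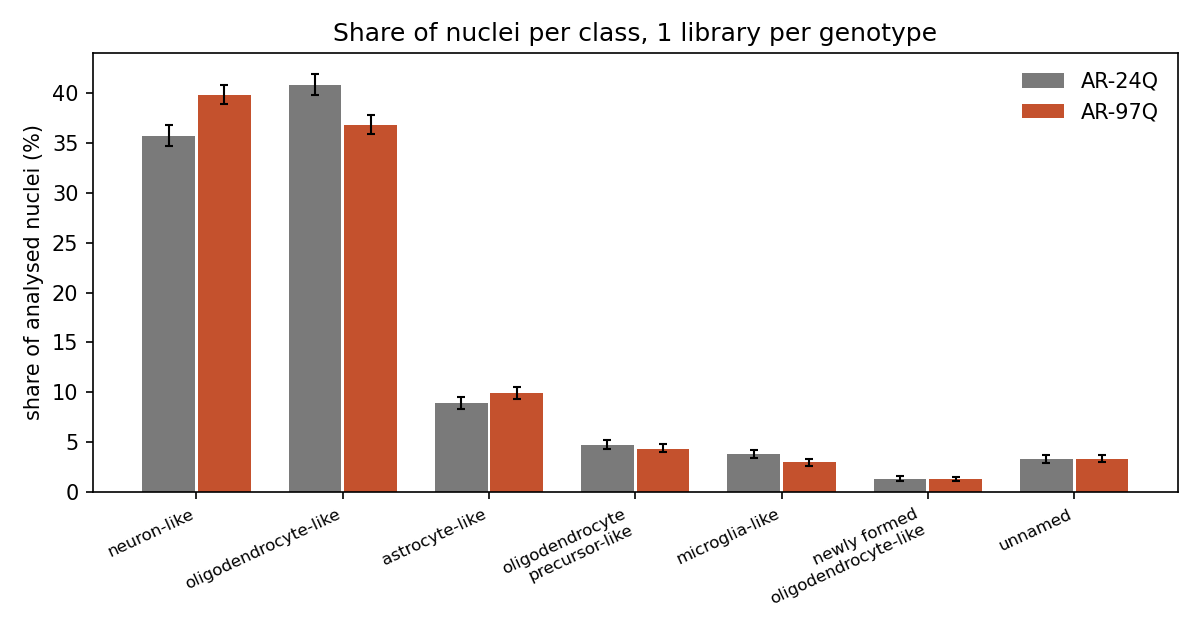
Share of analysed nuclei (%) per class in the AR-24Q (grey) and AR-97Q (orange) libraries, with bars for the share and lines for the exact 95% binomial interval. Neuron-like nuclei stood at 35.7% and 39.8% and oligodendrocyte-like nuclei at 40.9% and 36.9%.

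Counts of Ar, the mouse androgen receptor gene, were higher in AR-97Q, with larger ratios in astrocyte-like nuclei and those of the oligodendrocyte line than in neuron-like nuclei. Over all nuclei Ar stood at 32.0 CPM in AR-24Q and 73.1 CPM in AR-97Q, a ratio of 2.28 (2.16 to 2.42). In neuron-like nuclei the ratio was 1.80 (1.69 to 1.91), from 45.7 to 82.1 CPM. In astrocyte-like nuclei 21 counts in AR-24Q stood against 506 in AR-97Q, a ratio of 15.9 (10.3 to 25.9), and the 141 CPM (129 to 154) reached in AR-97Q lay above the neuronal level. In oligodendrocyte-like nuclei 24 counts stood against 401, a ratio of 12.9 (8.53 to 20.3). The ratio was 8.84 (4.77 to 18.2) in oligodendrocyte precursor-like nuclei, with 11 and 119 counts, and 20.3 (6.71 to 100) in newly formed oligodendrocyte-like nuclei, with 3 and 86. In cholinergic or motor neuron-like nuclei, a class that joins a subcluster of 33 and 39 nuclei without Mnx1 or Vipr2 among its detected markers and a subcluster of 16 and 18 nuclei with both, Ar stood at 59.3 CPM (45.5 to 76.0) in AR-24Q and 163 CPM (140 to 188) in AR-97Q. The astrocyte-like ratio was 32.1 after thinning, 25.8 at most 1% mitochondrial UMIs and 25.7 at a Leiden resolution of 0.5. These settings also change which nuclei are counted. Their ratios have no interval here, and the AR-24Q side of the main ratio rested on only 21 counts. The class held 723 and 1019 nuclei in the main setting. It held 637 and 910 at most 1% mitochondrial UMIs and 636 and 909 at a resolution of 0.5.

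Ar (ENSMUSG00000046532) lies on chromosome X of GRCm38 from 98148769 to 98323215, and transcripts of the human transgene that aligned to it would be counted with it. Microglia-like nuclei served as the reference for free RNA. They held 0 Ar counts in 513935 UMIs of AR-24Q, which allows up to 7.18 CPM, and 4 in 491791 of AR-97Q (8.13 CPM, 2.22 to 20.8), at median depths of 1598 and 1560 UMIs. In AR-97Q the upper bound in microglia-like nuclei lay below the lower bound of 26.5 CPM in oligodendrocyte-like nuclei, at a median of 2953 UMIs. Endothelial-like, pericyte or smooth muscle-like, ependymal-like and fibroblast-like nuclei held more Ar, from 63.9 to 178 CPM in AR-97Q on 5 to 11 counts. In AR-24Q they held 16.5 to 103 CPM on 1 to 4 counts. Over all nuclei Xist, the RNA that silences an X chromosome in females, stood at 0.269 and 0.275 CPM. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y had ratios of 0.972, 0.984, 1.10 and 1.01, of which that of Kdm5d (1.05 to 1.16) exceeded counting error. Ddx3y stood at 0.905 (0.842 to 0.972) in neuron-like nuclei and Kdm5d at 1.22 (1.09 to 1.37) in oligodendrocyte-like nuclei. The gene model Gm47283, placed on the Y chromosome, was lower in AR-97Q in each of the 8 classes, with ratios from 0.365 to 0.460. Whether its sequence is specific to the Y chromosome was not examined. The sex-linked list had a median log2 ratio of -0.06 (percentile 23.2) in neuron-like and 0.05 (71.6) in oligodendrocyte-like nuclei, but 0.31 (0.12 to 0.43, percentile 99.2) in astrocyte-like nuclei, where each of the 4 measured members was higher, and -0.22 (-0.55 to 0.02, percentile 8.53) in microglia-like nuclei, where each was lower.

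**Figure D2:**
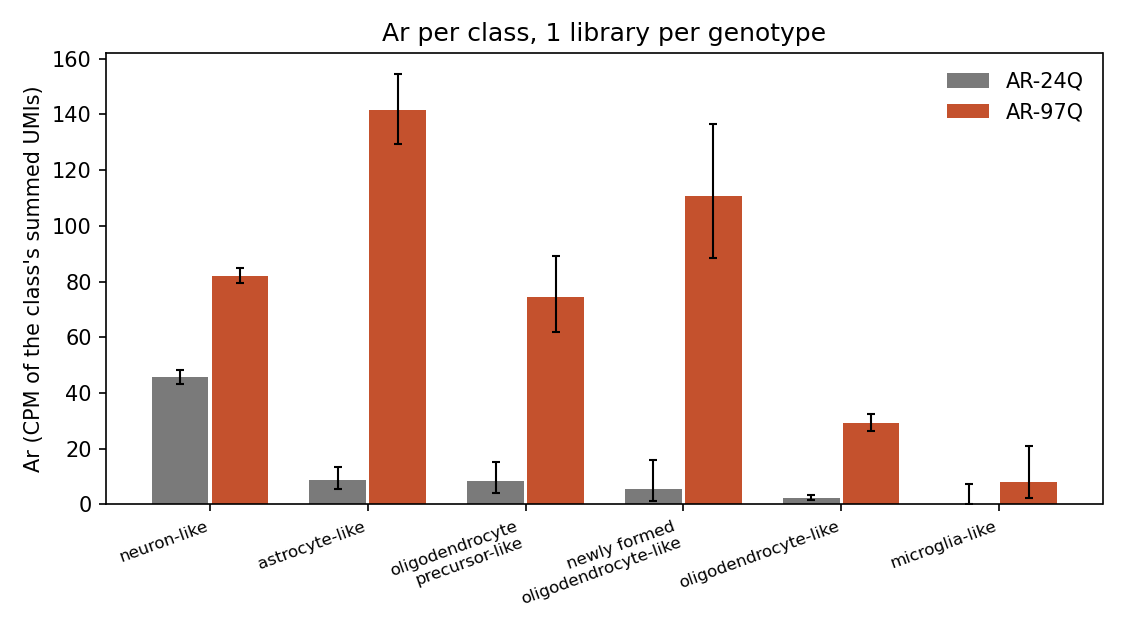
Ar in CPM of each class's summed UMIs in the AR-24Q (grey) and AR-97Q (orange) libraries, with exact 95% Poisson intervals as lines. In AR-97Q the astrocyte-like bar at 141 CPM stands above the neuron-like bar at 82.1 CPM, and the microglia-like bar is at 8.13 CPM.

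In neuron-like nuclei, 2902 in AR-24Q and 4096 in AR-97Q, few single genes besides Ar differed by the naming threshold. Each of the 21 measured genes of cholesterol synthesis was lower in AR-97Q, while 24 of 27 heat shock and chaperone genes were higher. The other genes past the naming threshold were Ptgds (prostaglandin D synthase) with a ratio of 1.73 (1.64 to 1.82), Mt1 (a metallothionein) with 1.52 (1.42 to 1.63) and Fhit with 0.657 (0.629 to 0.686). Ptgds is abundant in oligodendrocytes, and the list of free RNA from abundant cell types was itself higher in neuron-like nuclei, with a median log2 ratio of 0.14 (percentile 100). A subcluster of unnamed kind led by Plp1 and Ptgds held 138 and 279 nuclei. Lists of ion channels (0.01, percentile 74.9), glutamate, GABA and glycine receptors (-0.02, 22.2), synaptic adhesion (-0.01, 36.8) and presynaptic release genes (0.01, 84.3) had medians near 0. Neurofilament and axonal transport genes stood at 0.05 (99.0), with Nefl at 1.25-fold (1.19 to 1.31) and Nefm at 1.22-fold (1.18 to 1.27). Nefl and Nefm also belong to the free RNA list. Signs of cytoplasmic RNA were higher too, with mitochondrially encoded genes at 0.76 and ribosomal protein genes at 0.12. Genes of motor neuron identity had a median of -0.18 (percentile 0.02), with 14 of 20 lower, among them Prph, a neurofilament of motor neurons, at 0.608-fold (0.517 to 0.715). Cholinergic or motor neuron-like nuclei were 49 of the 2902 neuron-like nuclei in AR-24Q and 57 of the 4096 in AR-97Q, and the list stood at -0.18 (-0.35 to 0.01, percentile 1.28) in excitatory-like and 0.09 (-0.17 to 0.17, percentile 91.1) in inhibitory-like neurons. Slc18a3, the vesicular acetylcholine transporter, stood the other way at 1.54-fold, on 23 and 49 counts (0.920 to 2.65).

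Among excitatory-like neurons, Ptgds (1.92), Ar (1.78), Pcsk2os2 (1.58), Il1rapl2 (1.54) and Mt1 (1.54) had the highest ratios. Nts, which encodes neurotensin, was lower at 0.630-fold (0.601 to 0.660), against 1.75-fold over all other nuclei, and Col5a2 was lower at 0.649-fold against 1.26. Nts leads excitatory-like subclusters with 103 and 100 and with 47 and 80 nuclei, and Col5a2 leads a subcluster with 54 and 46, of 1099 and 1558 excitatory-like nuclei in AR-24Q and AR-97Q. Ratios within these subclusters were not computed. Among inhibitory-like neurons, Ar (1.72) and Stmn1 (1.52), a tubulin-binding protein, were higher. Gfra1, a receptor of glial-derived neurotrophic factor, was lower at 0.586-fold, Fhit at 0.619-fold and Setx, an RNA and DNA helicase gene linked to motor neuron disease, at 0.630-fold (0.571 to 0.695), against 0.713 over all other nuclei. Pcsk2os2 lies opposite Pcsk2, and Il1rapl2, Gfra1 and Fhit also overlap genes of the other strand, so counts of these genes are uncertain.

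In oligodendrocyte-like nuclei, Phyhd1, a dioxygenase gene of the phytanoyl-CoA hydroxylase family, was 5.56-fold higher in AR-97Q (4.58 to 6.80), against 1.33-fold over all other nuclei. Grik1, which encodes a kainate-type glutamate receptor subunit, was lower at 0.449-fold (0.424 to 0.475), against 0.896 elsewhere. Ion channel genes were higher as a group, heat shock and chaperone genes were higher, and cholesterol synthesis genes were lower. Phyhd1 (ENSMUSG00000079484) lies on chromosome 2 from 30266203 to 30282149 and went from 118 counts (11.2 CPM) to 851 (62.2 CPM). Grik1 (ENSMUSG00000022935) lies on chromosome 16 from 87895900 to 88290265 and went from 3221 counts (305 CPM) to 1876 (137 CPM). These sums covered 3320 nuclei with 10552251 UMIs in AR-24Q and 3789 nuclei with 13688273 UMIs in AR-97Q, and 3517 genes could be ranked.

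The other higher genes were Kcnma1, a calcium-activated potassium channel (2.15, 1.89 to 2.44), the phospholipase Pnpla7 (1.86), Lingo2 (1.82), the dystrobrevin Dtnb (1.76), Fbxw15 (1.72), Galnt17 (1.71), Fhit (1.68), Anxa5 (1.67), the protease Klk6 (1.65), the heat shock protein Hspa4l (1.63) and Pakap (1.62). Fbxw15 had a like ratio of 1.81 over all other nuclei, whereas Fhit stood at 0.711 there. Pnpla7 was also higher there, at 1.34. The other lower genes were Tmem132d (0.613), the adhesion molecule Mcam (0.618), Snrpf (0.619), Epb41l4a (0.643), Sppl2b (0.646), Csmd2 (0.653), Crtac1 (0.654), Grik4, another kainate receptor subunit (0.659), Synpr (0.660) and Arhgap33 (0.661). Mcam and Snrpf were also lower over all other nuclei, at 0.763 and 0.790. Phyhd1 and Pnpla7, and Ptgds and Setx named in neuronal classes, all lie on chromosome 2 between 24976033 and 30282149. Outside neuron-like nuclei Ptgds stood at 1.35, and outside inhibitory-like nuclei Setx stood at 0.713. Whether this shared stretch bears on their ratios was not tested. Kcnma1, Dtnb, Fbxw15, Galnt17, Fhit, Pakap, Tmem132d, Mcam, Snrpf, Csmd2 and Crtac1 overlap other annotated genes, and their counts are uncertain to that extent.

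An oligodendrocyte-like cluster rich in mitochondrial RNA (0.713% of its UMIs) held 42 nuclei of AR-24Q and 295 of AR-97Q, and several results rest on it. Clustered without cytoplasmic genes and without the cluster's leading genes, the cluster that took most of these nuclei held 62 and 297. Klk6 is among its leading genes. Without it Anxa5 stood at 0.780, Klk6 at 0.951 and Pakap at 1.10, while Phyhd1 stood at 6.48, Kcnma1 at 2.35 and Grik1 at 0.441. The mitochondrially encoded list had a median log2 ratio of 1.57 with the cluster and 0.02 without it, the ribosomal protein list 0.26 and -0.07, and nuclear genes of oxidative phosphorylation 0.29 and -0.02. Genes of disease-associated oligodendrocytes stood at 0.29 and -0.07, and those of the mature state MOL2, common in white matter of the cord, at 0.56 and -0.27. Autophagy and proteasome genes stood at 0.03 and -0.07, the free RNA list at 0.15 and -0.03, and interferon response genes at 0.23 and 0.02.

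**Figure D3:**
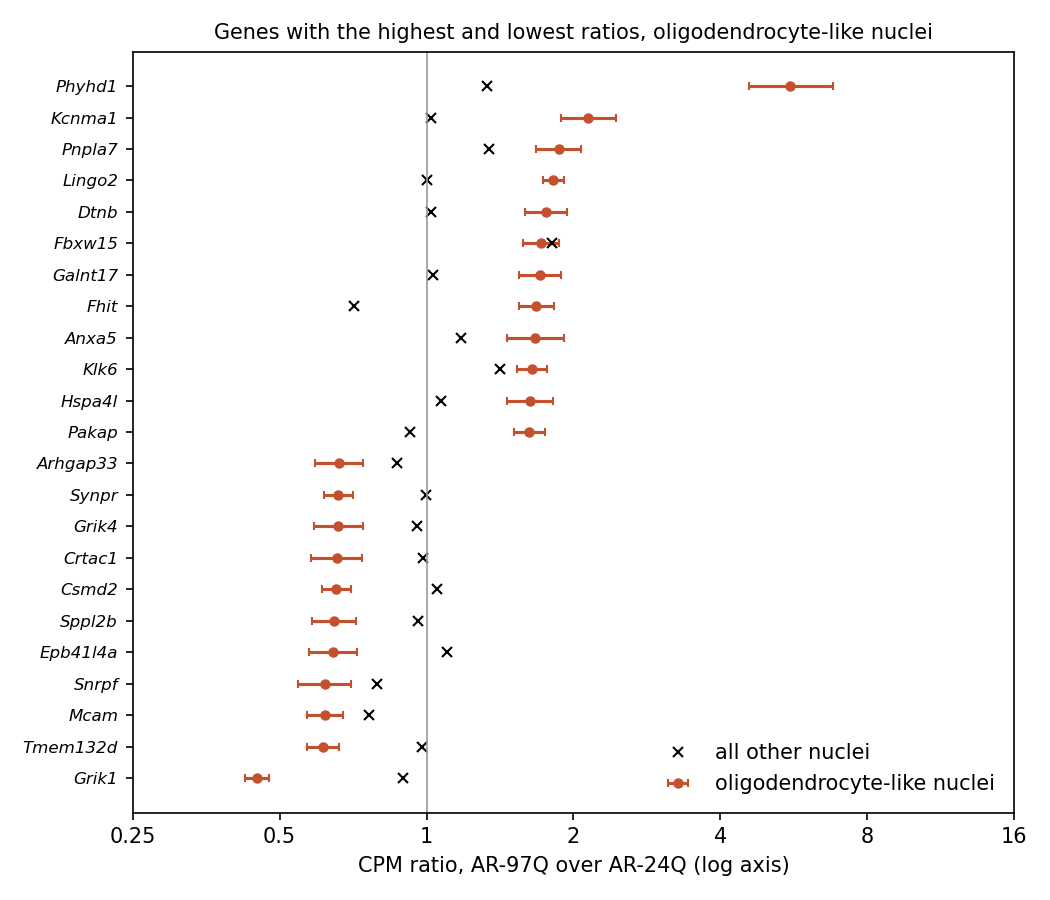
Ratio of CPM (AR-97Q over AR-24Q, log axis) of the genes named in oligodendrocyte-like nuclei, as points with 95% conditional binomial intervals, and of the same genes over all other nuclei as crosses. Phyhd1 at 5.56 and Grik1 at 0.449 lie farthest from 1, and Fbxw15 has crosses and points at like values.

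Ion channel genes in oligodendrocyte-like nuclei had a median log2 ratio of 0.23 (0.14 to 0.32, percentile 100), with 31 of 39 measured members higher, and 0.22 without the mitochondria-rich cluster. Kcnd3 stood at 2.20-fold (1.30 to 3.86) on 20 and 57 counts, and Scn2a and Fam155a at 0.840-fold and 0.774-fold. Synaptic adhesion genes stood at 0.09 (98.4), led by Lingo2 and Dlgap1 (1.60), and at 0.19 (100) without that cluster. Glutamate, GABA and glycine receptors stood at 0.04 (55.4) and without it at 0.14 (99.4), with 20 of 34 members higher. Neuronal RNA in these nuclei was weighed for Ar only and was not tested for the channel, adhesion and receptor lists. The myelin list had a median of -0.05 (percentile 24.7), with 14 of 21 members lower. Gjb1, a gap junction gene of myelinating cells, stood at 1.17-fold (1.09 to 1.26), Mag, the myelin-associated glycoprotein, at 0.849-fold (0.831 to 0.867) and Opalin at 0.735-fold (0.707 to 0.763). Without the mitochondria-rich cluster the myelin median was -0.11 (percentile 0.47), with 4 of 21 members higher, and averaged within clusters it was -0.12. Ermn, Mal, Plp1 and Trf of this list are among the leading genes of that cluster. The list of the mature states MOL5 and MOL6 had a median of -0.05 (32.6), and of -0.16 (0.70) without that cluster. Nuclear long non-coding RNAs had a median of 0.00 (48.7), among which Neat1 stood at 0.733-fold (0.718 to 0.747).

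Genes of cholesterol synthesis were lower in AR-97Q in neuron-like, oligodendrocyte-like, oligodendrocyte precursor-like and astrocyte-like nuclei. The median log2 ratio was -0.26 (-0.32 to -0.24) in neuron-like, -0.13 (-0.18 to -0.08) in oligodendrocyte-like, -0.38 (-0.56 to -0.22) in precursor-like and -0.30 (-0.34 to -0.17) in astrocyte-like nuclei, at percentiles 0, 0.04, 0.01 and 0. Of 21 measured members, 21, 17, 17 and 18 were lower. Insig1, which acts in the control of the cholesterol regulator SREBP, stood at 0.698-fold (0.631 to 0.773) in neuron-like and 0.782-fold (0.718 to 0.851) in oligodendrocyte-like nuclei. Ldlr, the receptor that takes up low density lipoprotein, stood at 0.433-fold (0.305 to 0.608) in precursor-like nuclei. Hmgcs1 and Mvd, enzymes of the mevalonate pathway, stood at 0.622-fold (0.554 to 0.698) and 0.587-fold (0.454 to 0.757) in astrocyte-like nuclei. Members above 1 included Fdps at 1.17-fold (1.09 to 1.26) in oligodendrocyte-like nuclei. In newly formed oligodendrocyte-like nuclei the median was -0.19 (-0.35 to -0.01, percentile 8.69), with 7 of 21 members higher. Microglia-like nuclei measured 10 members with a median of -0.04 (-0.51 to 0.32), where a shift of this size was not detectable. Without the mitochondria-rich cluster the oligodendrocyte-like median was -0.39 and all 21 members were lower.

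Heat shock and chaperone genes were higher in AR-97Q in oligodendrocyte-like, newly formed oligodendrocyte-like and neuron-like nuclei. The median log2 ratio was 0.40 (0.32 to 0.43) in oligodendrocyte-like nuclei, with 22 of 26 members higher, and 0.15 (0.10 to 0.19) in neuron-like nuclei, both at percentile 100. Hspa1b, an inducible member of the Hsp70 family, had 6 and 56 counts in oligodendrocyte-like nuclei, a ratio of 7.20 (3.11 to 20.4), and Hspa1a stood at 1.71-fold (1.07 to 2.81). Hsf1, the transcription factor that drives these genes, stood at 0.830-fold (0.707 to 0.975) there and 0.885-fold (0.814 to 0.962) in neuron-like nuclei. In newly formed oligodendrocyte-like nuclei the median was 0.22 (0.05 to 0.42, percentile 99.9), with 17 of 21 members higher. The medians were 0.08 (-0.02 to 0.22) in precursor-like, 0.08 (0.02 to 0.25) in astrocyte-like and 0.19 (-0.02 to 0.49) in microglia-like nuclei. Signs of cytoplasmic RNA went the same way in neuron-like nuclei, where the ribosomal protein list stood at 0.12, nuclear genes of oxidative phosphorylation at 0.15 and mitochondrially encoded genes at 0.76. In oligodendrocyte-like nuclei without the mitochondria-rich cluster the heat shock median was 0.28 and the ribosomal protein median -0.07.

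**Figure D4:**
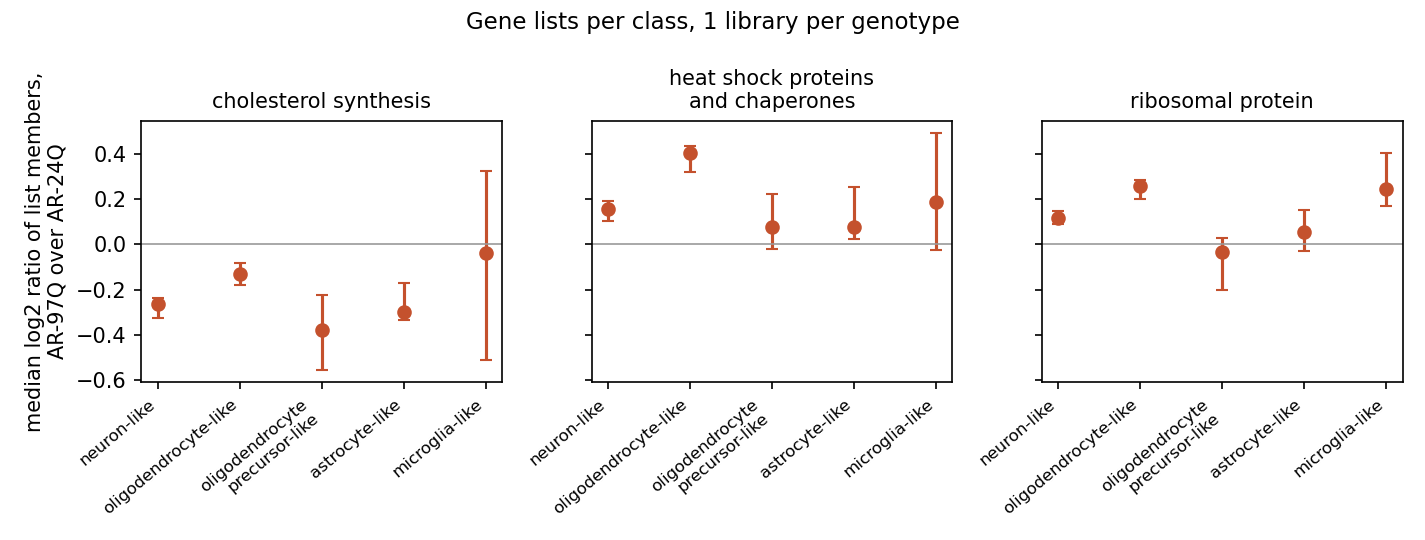
Median log2 ratio (AR-97Q over AR-24Q) of the cholesterol synthesis, heat shock and ribosomal protein lists in 5 classes, as points with lines for the 95% interval of Poisson draws. Cholesterol synthesis lies below 0 in neuron-like (-0.26), oligodendrocyte-like (-0.13), precursor-like (-0.38) and astrocyte-like (-0.30) nuclei, and the heat shock list is highest in oligodendrocyte-like nuclei (0.40).

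In oligodendrocyte precursor-like nuclei Ar, Lingo2 and the median of the channel list were higher, as in oligodendrocyte-like nuclei. Which channel genes were higher in both classes was not compared. Besides Ar, the highest ratios were those of Hs6st3, a heparan sulfate sulfotransferase (2.43, 1.60 to 3.77), the potassium channel partner Kcnip4 (1.94), Pex5l (1.91) and Lingo2 (1.87, 1.46 to 2.42). The lowest were Ldlr, Slc35b2 (0.495), Zfp512b (0.508), Ly6h (0.516) and Mid1 (0.519). Mid1 was also lower over all other nuclei, at 0.625. Ion channel genes had a median log2 ratio of 0.14 (0.08 to 0.21, percentile 100), with 30 of 40 members higher. Newly formed oligodendrocyte-like nuclei had a median of -0.04 (-0.16 to 0.11). Neuronal RNA was not tested as a source of the precursor-like shift or of Kcnip4, an abundant neuronal transcript. Cell cycle genes were measured for only 6 of 18 members and all 6 were lower, with a median of -0.73 (-1.18 to -0.24), and Top2a, a topoisomerase of dividing cells, stood at 0.418-fold (0.241 to 0.705) on 45 and 23 counts. The list of precursor maintenance and differentiation stood at 0.00 (33.5), with Olig2 at 0.719-fold (0.626 to 0.826) and Sox6 at 1.14-fold (1.08 to 1.20). In the same nuclei mitochondrially encoded genes stood at -0.35 (-0.51 to -0.16) and the free RNA list at 0.20 (0.03 to 0.33). In newly formed oligodendrocyte-like nuclei, with 105 and 131 nuclei, Slain1 (2.49), Slc24a2 (2.24), Pak7 (2.11), Itgb3bp (2.10) and the potassium channel Kcna1 (1.99, 1.48 to 2.72) were highest. Snhg20 (0.440), Arhgef3 (0.472), Sntg1 (0.494), Rtkn2 (0.503) and Nxn (0.507) were lowest there. Hs6st3, Kcnip4, Pex5l, Zfp512b, Mid1, Slain1, Pak7, Itgb3bp and Rtkn2 overlap other genes, and their counts are uncertain.

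Astrocyte-like nuclei held the highest Ar level of the classes compared by gene in AR-97Q, and further genes were higher by over 2-fold. BC055402 stood at 4.54-fold (3.24 to 6.53) and Tafa1, a secreted chemokine-like protein, went from 109 to 338 CPM (ratio interval 2.71 to 3.56). Slc24a4, a sodium, calcium and potassium exchanger, stood at 2.54-fold (2.09 to 3.12) and the non-coding RNA Lncbate1 at 2.44-fold (1.89 to 3.18). Slc16a6 (0.412, 0.307 to 0.551), Tmem117 (0.536), Adamtsl1 (0.552), Aacs, an acetoacetyl-CoA synthetase (0.560), and Smad2, a mediator of TGF-beta signals (0.565), were lowest. BC055402 (ENSMUSG00000101429) lies on chromosome 1 from 57200645 to 57214993, and Tafa1 (ENSMUSG00000059187) on chromosome 6 from 96113154 to 96657198. Genes of astrocyte transport stood at a median log2 ratio of 0.00 (35.0), with the glutamine synthetase Glul at 1.38-fold (1.24 to 1.55) and the water channel Aqp4 at 0.803-fold (0.759 to 0.850). Reactive astrocyte genes stood at -0.13 (-0.29 to 0.20), with 7 of 11 measured members lower, and TGF-beta and BMP genes at -0.11 (-0.20 to 0.01). Synaptic adhesion genes stood at -0.13 (-0.19 to -0.07, percentile 0.09). Tafa1, Slc24a4, Lncbate1, Slc16a6, Tmem117 and Adamtsl1 overlap other genes, and their counts are uncertain.

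Microglia-like nuclei had lower counts of the genes that mark resting microglia. All 13 measured homeostatic genes were lower in AR-97Q, with a median log2 ratio of -0.24 (-0.30 to -0.14, percentile 0.015). Olfml3 stood at 0.604-fold (0.465 to 0.782) and Tmem119 at 0.695-fold (0.566 to 0.852), while Fcrls (0.995) and Sall1 (0.991) were near 1. Lyz2, the lysozyme of myeloid cells, was the highest named gene at 2.33-fold (1.58 to 3.49), followed by Ank (1.96), Kcnip4 (1.87), Cntnap2 (1.82) and Rgs2 (1.78). Nlgn1 (0.488), the fructose transporter Slc2a5 (0.489), Sgk1 (0.515), Map2k6 (0.517) and Itm2c (0.536) were lowest. Slc2a5 had a like ratio of 0.463 over all other nuclei, so its lower level was not particular to this class. Disease-associated microglia genes stood at 0.08 (-0.08 to 0.23), with the lipid carrier Apoe at 1.49-fold (1.30 to 1.71), and interferon response genes at -0.23 (-0.31 to 0.20). Ribosomal protein genes were higher in the same nuclei, at 0.25 (percentile 100), and so was the free RNA list, at 0.23 (99.4). Kcnip4, Cntnap2 and Nlgn1 are abundant neuronal transcripts, and Ank, Kcnip4 and Nlgn1 overlap other genes. Kcnip4 stood at 0.706 and Itm2c at 1.06 after thinning, and Nlgn1 stood at 1.43 with doublet calls kept in. The sums of the main setting covered 307 and 303 nuclei at median depths of 1598 and 1560 UMIs. Thinning left out nuclei under 2541 UMIs, which is above both medians. The thinned values therefore rest on the deeper nuclei of the class and have no interval here.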

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

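No paired analysis was possible because each genotype has 1 library, and both carry only replicate number 1. The tests without the oligodendrocyte-like cluster of highest mitochondrial share, without the neuron-like cluster of lowest depth, and with ratios averaged within clusters were chosen only after the results had been seen. Over all settings, 799 of 862 recomputed gene ratios stayed within their counting interval, 57 moved beyond it and 6 reversed. Of 1090 list medians 1006 stayed, 69 moved and 15 reversed. Of 89 share differences 88 stayed. Where a value below moved, the cause was not tested unless the setting itself shows it.

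With doublet calls kept in, the neuron-like share differed by 1.99 percentage points and Nlgn1 stood at 1.43 in microglia-like nuclei. At most 1% mitochondrial UMIs gave oligodendrocyte-like medians of -0.19 for cholesterol synthesis and 0.22 for disease-associated genes. Scaling to a median ratio of 1 gave a myelin median of -0.082. The mean over nuclei gave -0.082 for myelin, -0.30 for cholesterol synthesis, 0.11 for disease-associated genes and -0.0054 for autophagy in oligodendrocyte-like nuclei, and -0.0067 for autophagy in neuron-like nuclei.

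Thinning gave a ratio of genes per nucleus of 1.00. It gave Ar ratios of 1.98 in neuron-like and 32.1 in astrocyte-like nuclei, which held only 21 AR-24Q counts in the main setting. It gave -0.064 for myelin, -0.21 for cholesterol synthesis and 0.18 for disease-associated genes in oligodendrocyte-like nuclei. In microglia-like nuclei, of which thinning kept only those with at least 2541 UMIs, Kcnip4 stood at 0.706 and Itm2c at 1.06. Of the 23 genes named in oligodendrocyte-like nuclei, 14 were also named after thinning, 14 without the mitochondria-rich cluster, 10 at a CPM of 100 and a summed count of 400, and 5 at a CPM of 10 and a summed count of 50, where more low genes compete for the same places.

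Without the mitochondria-rich cluster, whose own genes this removes, medians in oligodendrocyte-like nuclei were -0.11 for myelin, -0.39 for cholesterol synthesis, 0.28 for heat shock genes, -0.066 for autophagy, -0.020 for oxidative phosphorylation, -0.068 for disease-associated genes, -0.27 for MOL2 genes, -0.072 for ribosomal protein genes and -0.035 for the free RNA list. Anxa5 stood at 0.780 and Klk6 at 0.951. Averaged within clusters, the same lists stood at -0.12, -0.35, 0.26, -0.053, -0.011, -0.022, -0.052, -0.078 and -0.038, and Anxa5 at 0.945. Without the neuron-like cluster of lowest depth, neuron-like values stayed within their intervals, with Ar at 1.80 and Ptgds at 1.73. Without a minimum count the sex-linked list stood at -0.15 in oligodendrocyte-like nuclei, and with a minimum of 100 cholesterol synthesis stood at -0.58 in precursor-like nuclei.

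Of the 8 classes compared by gene, microglia-like and newly formed oligodendrocyte-like nuclei had the lowest summed UMIs, with 513935 and 491791 and with 549596 and 776970, and the fewest ranked genes, 2132 and 2273.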

Other observations

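The tests on free RNA, on transgene transcripts, on cytoplasmic RNA over the whole library, on depth for cholesterol genes and on clusters for cholesterol genes were chosen only after their results had been seen. Androgen and steroid responsive genes were higher in oligodendrocyte-like nuclei, with a median log2 ratio of 0.19 (0.15 to 0.29, percentile 99.8), and in astrocyte-like nuclei, with 0.16 (0.07 to 0.30, percentile 97.0). Fkbp5, a co-chaperone that steroid receptors induce, stood at 3.47-fold (2.14 to 5.91) in astrocyte-like nuclei and at 0.885-fold (0.814 to 0.964) in neuron-like nuclei. Plin4, a lipid droplet protein, had 45 and 367 counts in oligodendrocyte-like nuclei (6.29-fold, 4.60 to 8.77) and Sult1a1, a sulfotransferase, 17 and 65 (2.95-fold, 1.71 to 5.36). Plin4, Cdkn1a and Sgk1 also belong to the disease-associated oligodendrocyte list, which was not higher without the mitochondria-rich cluster. Values of the androgen list and of these genes without that cluster are not given here. In precursor-like nuclei the list stood at -0.11 (percentile 17.0), with the steroid-responsive factor Zbtb16 at 0.596-fold (0.474 to 0.746). In newly formed oligodendrocyte-like nuclei the list stood at -0.08 (38.4). The neuron-like median was 0.09 (97.6) and the microglia-like median 0.18 (85.5).

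Genes of the unfolded protein response stood at 0.22 (0.04 to 0.39, percentile 99.6) in astrocyte-like nuclei, with Herpud1 at 1.62-fold (1.27 to 2.08) and Hspa5, the chaperone BiP, at 1.39-fold (1.18 to 1.65). The medians were 0.17 (98.8) in oligodendrocyte-like (0.10 without the mitochondria-rich cluster), 0.17 (98.8) in precursor-like, 0.23 (98.6) in newly formed oligodendrocyte-like, 0.08 (98.4) in neuron-like and 0.10 (79.6) in microglia-like nuclei. Sqstm1, an adaptor of autophagy, stood at 1.83-fold (1.39 to 2.44) in astrocyte-like nuclei, while the autophagy and proteasome list stood at -0.02 (31.1) there, and at 0.08 (0.02 to 0.11) in neuron-like nuclei, or -0.0067 as a mean over nuclei. Cdkn1a, an inhibitor of the cell cycle, stood at 2.45-fold (1.84 to 3.30) in oligodendrocyte-like nuclei, with the DNA damage list at 0.05 (52.6) there, -0.06 without the mitochondria-rich cluster, and -0.06 (18.8) in neuron-like nuclei. Genes of mitochondrial quality stood at 0.12 (92.2) in oligodendrocyte-like and -0.01 (47.7) in neuron-like nuclei. Extracellular matrix genes stood at 0.41 (0.00 to 0.65) in oligodendrocyte-like nuclei, or 0.19 without that cluster, led by Lamb1 at 2.72-fold (1.66 to 4.64), and at -0.08 in astrocyte-like nuclei. Immediate early genes stood at -0.16 (-0.25 to 0.02, percentile 0.80) in neuron-like and -0.38 (-0.62 to 0.08) in astrocyte-like nuclei.

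A pair of transcripts kept out of the ranking, chosen here after their values were seen, were lower in AR-97Q in each of the 8 classes. Gm47283, which lies on the Y chromosome from 90784738 to 90816464, had ratios from 0.365 in precursor-like to 0.460 in microglia-like nuclei. AC149090.1 had ratios from 0.445 in newly formed oligodendrocyte-like to 0.639 in inhibitory-like nuclei.

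Higher Ar in astrocyte-like and oligodendrocyte-line nuclei of AR-97Q was weighed against carried-over RNA. Free RNA would reach microglia-like nuclei too, yet Ar stood there at 8.13 CPM (2.22 to 20.8), below the lower bound of 26.5 CPM in oligodendrocyte-like nuclei. The comparison rests on microglia-like nuclei alone, since endothelial-like, pericyte or smooth muscle-like, ependymal-like and fibroblast-like nuclei held 63.9 to 178 CPM on 5 to 11 counts. Neuronal RNA in glial nuclei would bring neuron markers along with Ar. The medians of 11 neuron markers stood at 2.29%, 13.2% and 3.26% of their neuronal level in oligodendrocyte-like, precursor-like and astrocyte-like nuclei, and their upper quartiles at 5.34%, 26.6% and 19.7%, whereas Ar stood at 35.7%, 90.9% and 172%; a lone marker, Gabrb2 in precursor-like nuclei, stood above Ar at 133%. Whether the added counts are transcripts of the human transgene cannot be told apart from mouse Ar at the ratio of 2.28 over all nuclei, since the tables hold 1 sum per gene, and a difference between the lines in where Ar or the transgene is active stays open and untested.

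The mitochondria-rich oligodendrocyte-like cluster, with 42 and 295 nuclei, may reflect a technical split. When nuclei were clustered again without 165 cytoplasmic genes, 84.9% of its 337 nuclei came together in 1 cluster whose share was 5.11 times as large (3.79 to 6.99) in AR-97Q, and between 3.18 and 5.61 times as large when its leading genes were left out too. After thinning, the corresponding ratio was 8.89 (5.79 to 14.3). More cytoplasmic RNA in the whole AR-97Q library would raise mitochondrially encoded genes in each class, but their median was 0.058 (-0.09 to 0.19) in astrocyte-like and -0.35 in precursor-like nuclei, although it was 0.76 in neuron-like and 0.33 (0.00 to 0.60) in microglia-like nuclei, so more of it in some classes stays open. The genotype and the amount of white matter or of each cord region in a pool stay open and were not tested, and 1 library may hold a cluster of its own.

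Lower cholesterol synthesis genes in 4 classes may follow from depth or from the clusters that fill a class. After thinning, the medians were -0.31, -0.21, -0.37 and -0.26 in neuron-like, oligodendrocyte-like, precursor-like and astrocyte-like nuclei, the highest being -0.21 (-0.26 to -0.14). Averaged within clusters, the medians were -0.25 (-0.31 to -0.22) in neuron-like and -0.35 in oligodendrocyte-like nuclei. The genotype and other differences between the pools stay open and were not tested.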
